A study of Mus musculus with 12 samples.

How the data were processed

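RNA from fat grafts of C57BL/6 wild-type mice aged 16 weeks, collected at 8 weeks of grafting, was measured in 12 libraries, 4 in each of 3 groups named control, CAL and CAL_Dll4i after the sample labels. Total RNA was extracted with Trizol and libraries were made with a SureSelectXT RNA Direct kit, a method that enriches exonic sequence by capture, per the labels' protocols. Reads were aligned with HISAT2 and assembled with StringTie on the mouse genome build mm10, per the submitters' processing notes, which give no versions.

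The deposited table holds 19547 genes with 3 values per library: estimated counts, FPKM and TPM, per the file headers. The estimated counts deposited by the authors are whole numbers that are not scaled between libraries. Of the deposited counts, 1219 values equal 1, and 271 of these are worth under 0.5 read by the FPKM beside them. Whether low values were rounded up, or genes at 0 removed, before deposit is not given in the sources used here. The deposited FPKM values, scaled by the authors for transcript length and library size, were used only to check the counts. The deposited TPM values, also made by the authors, sum to 995156 to 998891 per library and were used only for the same check. Every gene has a count above 0 in all 12 libraries. Genes outside the table, such as Ucp1 and all 12 genes of the male tract list, were not analysed here.

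Counts were analysed in R 4.3.3 with edgeR 4.0.16: library sizes were scaled by TMM, genes with low counts were removed with filterByExpr at its defaults, and 18551 genes remained. The values were already whole, so rounding changed none of them. edgeR's quasi-likelihood test (robust, 1 coefficient per group, all 12 libraries in a shared fit) was run for CAL against control, CAL_Dll4i against CAL and CAL_Dll4i against control. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes carry a standard error (SE), and CPM values are TMM-normalised counts scaled to a common library size, given as mean ± SD over 4 libraries. Chromosome positions come from a RefSeq table of assembly GRCm38.p6, in which 18509 of the 18551 genes were found by gene ID.

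The gene lists (32 in all), the groups, the tests and the rule for naming genes were fixed before the data were examined. Of these lists, 30 had at least 5 tested genes and were tested with camera in limma 3.58.1 on voom values with its preset inter-gene correlation of 0.01, adjusted over the 30 lists. They cover Notch and angiogenic signalling, vessel and lymphatic cells, adipocytes and lipid metabolism, mitochondria, stroma and matrix, immune cells, neighbouring tissues (muscle, keratinocytes, mammary epithelium, Schwann cells, lymph node, red cells), and proliferation, hypoxia, immediate early, interferon and complement or lysosome genes. Each call was repeated with camera's estimated correlation and with fry's directional p. The mesothelial list had 3 tested genes and was used only for its share of counts. Shares of counts per list were compared by a two-sided exact permutation test over the 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286.

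Named genes are, per comparison, up to 10 called genes per direction without overlap between groups (with fewer than 5 passing, the 5 with the smallest p per direction, said not to pass), 20 genes fixed for the study's subject, and up to 4 genes with the smallest p of each list called. This gave 174 distinct genes, and results for a few genes are not reported here. The correlation of fold changes between comparisons that share libraries was set beside 20 simulations of unchanged groups and beside splits of the shared libraries.

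Alternatives were RLE and upper-quartile scaling, no filter and a filter at 1 CPM in 4 libraries, DESeq2 1.42.0, voom with sample weights, only the groups compared, the replicate number as a block, summed symbols, neighbouring-tissue genes left out, a test against a fold of 1.2, and each library left out in turn. Further settings were chosen after seeing the data: leaving out 3 libraries with muscle RNA, muscle and keratinocyte covariates, the 18S rRNA share as a covariate, and protein-coding genes without Lars2.

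The test code was checked on simulated counts drawn from these libraries' means and sizes with 200 changed genes. For CAL against control (18475 simulated genes), edgeR recovered 24.2% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 89.2% of those changed 4-fold, with 8 false calls. DESeq2, on all 18551 genes, recovered 41.8%, 67.2% and 92.4% there, with 49 false calls. For CAL_Dll4i against CAL (18483 genes), edgeR recovered 29.9%, 58.2% and 83.1% with 2 false calls, and for CAL_Dll4i against control (18489 genes) 37.3%, 53.7% and 89.1% with 2. DESeq2 made 31 and 37 false calls there. camera called 0 of 30 lists in each simulation, in which genes vary independently. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.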

Results

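The series measures gene expression in mouse fat grafts. The CAL group (cell-assisted lipotransfer) received added ASC, the usual abbreviation for adipose-derived stem or stromal cells, and the CAL_Dll4i group received ASC together with inhibition of Dll4. Total counts ran from 55883051 in CAL replicate 1 to 70804141 in CAL_Dll4i replicate 4, and the biological coefficient of variation was 0.237. Library pairs correlated at r = 0.975 to 0.989 within groups (18 pairs) and at 0.970 to 0.989 between groups (48 pairs), across genes, which are not independent replicates. CAL_Dll4i replicate 3 correlated at 0.977 to 0.978 with its own group, and with CAL replicates 1 to 4 at 0.988, 0.988, 0.980 and 0.980. CAL replicate 3 correlated at 0.982 to 0.983 with its own group and at 0.986, 0.985, 0.980 and 0.987 with CAL_Dll4i replicates 1 to 4. With control replicates 1 to 4 CAL replicate 3 stood at 0.986, 0.989, 0.981 and 0.984. The labels describe separate samples and do not say whether each came from its own animal, so the p-values measure only the spread between these samples.

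Dll4, the endothelial Notch ligand that was targeted, had the highest levels in control grafts. It stood at 5.78 ± 0.836 CPM in control, 3.72 ± 0.536 in CAL and 4.42 ± 0.399 in CAL_Dll4i (mean ± SD, n = 4 each). Single libraries ran from 4.97 to 6.95 in control, from 3.01 to 4.22 in CAL and from 3.98 to 4.95 in CAL_Dll4i. Dll4 (chromosome 2, 119325784 to 119335666 on GRCm38, the assembly of mm10) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in none of the 3 comparisons, with adjusted p = 0.132, 0.713 and 0.714. DESeq2 called Dll4 lower in CAL against control (adjusted p = 0.00278) and in neither other comparison. The labels do not say how Dll4 was inhibited, so its RNA level does not test the treatment. The annotated lncRNA Gm14207 overlaps its start, which leaves a share of its counts uncertain.

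CAL against control asks what adding ASC does to RNA levels in the graft. Vsig8, which encodes a membrane protein with immunoglobulin domains, was the 1 gene called. It rose from 14.0 ± 1.61 CPM in control to 27.7 ± 2.32 CPM in CAL (mean ± SD, n = 4 each), 1.99-fold, or 0.99 ± 0.10 on the log2 scale. All 4 CAL libraries lay above all 4 controls, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00796. Vsig8 lies on chromosome 1 at 172555938 to 172563717. Without CAL replicate 1 its adjusted p was 0.0517, without the 3 libraries with muscle RNA 0.169, and with only control and CAL in the fit 0.0909.

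No gene was called lower in CAL by edgeR, while 1405 genes were lower and 1300 higher at an unadjusted p under 0.05, or 14.6% of 18551. At an adjusted p under 0.10, 27 genes were higher and 9 lower. DESeq2 called 349 higher and 284 lower, and voom with sample weights 69 higher and 19 lower. The groups did not overlap for 1364 genes (7.35%), where chance gives 2.86%. The 4 next smallest p-values among higher genes were those of Myh15 (2.34 ± 0.33, log2 fold change ± SE), Atp6v0a1 (0.41 ± 0.06), Hs6st1 (0.40 ± 0.07) and Axl (0.46 ± 0.07), none of which passed by edgeR. Among lower genes they were Phldb2 (-0.49 ± 0.07), Angpt2 (-0.81 ± 0.13), Ecrg4 (-1.86 ± 0.31), Tspan6 (-0.79 ± 0.14) and Tfpi2 (-1.18 ± 0.21), which did not pass by edgeR either. DESeq2 called all 9 (adjusted p = 3.79e-09 for Myh15 to 4.77e-05 for Tspan6), and voom with sample weights all but Ecrg4 (0.0331 to 0.0436). The count of called genes was 6 without control replicate 1 (Vsig8, Evl, Il13ra2, Tagln, Phldb2 and Arhgap39) and 2 without control replicate 4 (Vsig8 and Epha5). It was 0 without CAL replicate 1, 2 without CAL replicate 2 (Vsig8 and Axl) and 3 without CAL replicate 3 (Vsig8, Cd33 and F2r). Genes called only in these settings were singled out after their values were seen.

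**Figure D1:**
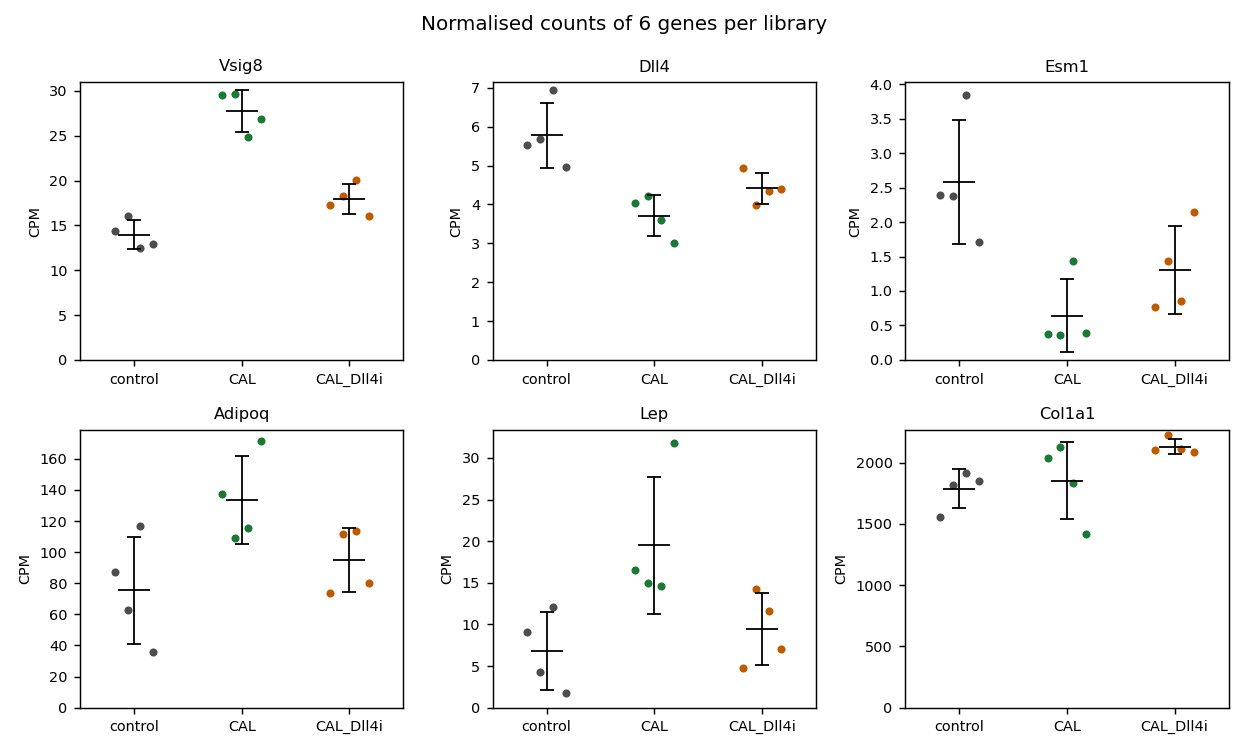
Normalised counts (CPM, vertical axis) of 6 genes in the 4 libraries of each group, with the mean and SD in black. Vsig8 lies at 24.9 to 29.7 CPM in CAL and at 12.5 to 16.0 in control, and Lep reaches 31.8 in CAL replicate 4.

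Adipocyte genes were higher in CAL than in control as a group. All 20 measured adipocyte markers had higher estimates, with a median log2 fold change of 0.95, and 17 of them passed adjusted over the list alone against 0 over all genes by edgeR (17 at an unadjusted p under 0.05). Car3 stood at 217 ± 79.4 and 398 ± 68.6 CPM in control and CAL, and Plin4, which coats lipid droplets, at 317 ± 144 and 647 ± 156, and DESeq2 called both (adjusted p = 0.0195 and 0.0203). The hormone genes Adipoq and Lep stood at 75.5 ± 34.5 and 133 ± 28.3 CPM and at 6.78 ± 4.65 and 19.5 ± 8.27. The camera adjusted p of the list was 3.24e-14, and the adjusted p = 0.690 with an estimated correlation. Lipogenesis genes were higher in 18 of 20 cases (median 0.34, camera adjusted p = 1.64e-06, adjusted p = 0.690 with an estimated correlation). Of these, 5 passed adjusted over the list alone (Scd1, Lpin1, Gpam, Mlxipl and Acacb, the last named after its value was seen) and 0 over all genes by edgeR, against 10 at an unadjusted p under 0.05. DESeq2 called Scd1 (adjusted p = 0.00441), Mlxipl (0.0294) and Lpin1 (0.0372), and voom with sample weights Scd1 (0.0436). Scd1, a fatty acid desaturase, stood at 463 ± 140 and 834 ± 93.3 CPM.

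Genes of fatty acid oxidation had higher estimates in CAL in 16 of 18 cases (median 0.11, camera adjusted p = 0.00152), for example Acadm at 135 ± 19.2 and 175 ± 19.8 CPM. Nuclear genes of oxidative phosphorylation were higher in 14 of 19 cases (median 0.08, camera adjusted p = 0.00181), and Atp5a1 (299 ± 10.3 and 350 ± 19.2 CPM) was the 1 gene that passed adjusted over the list alone. DESeq2 called Acadm (adjusted p = 0.0457) and Atp5a1 (0.000655), and voom with sample weights Atp5a1 (0.0436). Of the 13 mitochondrial-encoded genes, 12 were higher (median 0.09, camera adjusted p = 0.00654). All 3 lists had an adjusted p = 0.690 with an estimated correlation. Without CAL replicate 2 the camera adjusted p of the mitochondrial-encoded list was 0.0942, without the 3 libraries with muscle RNA 0.105 and with the muscle and keratinocyte covariates 0.0815.

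Vascular and Notch genes were lower in CAL than in control by camera. Of 21 Notch pathway genes, 14 were lower (median -0.16, camera adjusted p = 0.00959), and 3 passed adjusted over the list alone: Dll4, Efnb2 (9.37 ± 2.80 and 5.34 ± 1.10 CPM) and Unc5b (26.6 ± 3.66 and 14.8 ± 4.81 CPM). Hes1, a Notch target, had a log2 fold change of -0.40 and stood at 5.22 ± 0.333 CPM in CAL. Angiogenic signalling genes were lower in 18 of 26 cases (median -0.10, mean -0.28, camera adjusted p = 0.00654). Angpt2 (19.9 ± 3.15 and 11.4 ± 1.15 CPM), Vegfc (6.08 ± 0.606 and 4.09 ± 1.09) and the tip cell gene Esm1 (2.58 ± 0.898 and 0.641 ± 0.528) passed adjusted over that list alone, while Vegfa stood at 19.3 ± 3.11 and 18.3 ± 3.60. Endothelial markers were lower in 14 of 20 cases (median -0.19, camera adjusted p = 0.0224), and Ecscr and Esam passed adjusted over the list alone. Pecam1 stood at 133 ± 8.11 and 113 ± 23.5 CPM. These 3 lists had an adjusted p = 0.690 with an estimated correlation, and 0 of their genes passed over all genes by edgeR, against 8, 5 and 3 lower at an unadjusted p under 0.05. DESeq2 called Angpt2 (adjusted p = 2.81e-05), Ecscr (0.00133), Dll4 (0.00278), Esm1 (0.00592), Efnb2 (0.0121), Esam (0.0166), Unc5b (0.0196) and Vegfc (0.0294) lower, and voom with sample weights Angpt2 and Ecscr (0.0436 each).

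The camera adjusted p of the Notch list was 0.165 without CAL replicate 4. That of the angiogenic list was 0.121 without control replicate 3, 0.0643 without the 3 libraries with muscle RNA and 0.0738 with the muscle and keratinocyte covariates. Endothelial markers stood at 0.255 without control replicate 3, 0.605 without CAL replicate 3, 0.122 without CAL replicate 4 and 0.0798 with the 18S rRNA share as a covariate. Overlapping genes leave part of the counts of Angpt2 (within Mcph1) and Esm1 (a lncRNA) uncertain.

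Extracellular matrix genes had lower estimates in CAL in 26 of 30 cases (median -0.24, camera adjusted p = 2.33e-05, adjusted p = 0.690 with an estimated correlation). Fbn1, which encodes fibrillin, stood at 1275 ± 131 CPM in control and 945 ± 110 in CAL and was the 1 gene that passed adjusted over the list alone. Fn1 stood at 2193 ± 200 and 1668 ± 256 CPM, and Col1a1 at 1786 ± 158 and 1852 ± 316. All 10 measured neutrophil markers had lower estimates (median -1.11, camera adjusted p = 0.000145, adjusted p = 0.690 with an estimated correlation), and Mmp8, Mmp9, S100a8 and S100a9 passed adjusted over the list alone. S100a8 stood at 28.6 ± 14.1 and 13.3 ± 6.46 CPM. Inflammatory mediators were lower in 17 of 20 cases (median -0.32, camera adjusted p = 0.00356, adjusted p = 0.690 with an estimated correlation). Il6 stood at 5.41 ± 7.30 and 0.746 ± 0.168 CPM, with 16.4 CPM in control replicate 3, and Tnf at 19.5 ± 3.91 and 19.1 ± 4.46. Without the 3 libraries with muscle RNA the camera adjusted p of the inflammatory list was 0.237. DESeq2 called Mmp8 (adjusted p = 0.00467), Fbn1 (0.0102), Il6 (0.0283), Fn1 (0.0372) and Ccl7 (0.0469) lower. The inflammatory call also ended with the muscle and keratinocyte covariates (0.0838).

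Some other lists were also called by camera in CAL against control. B and plasma cell markers were higher in CAL in 15 of 16 cases (median 0.52, camera adjusted p = 0.00854) and mast cell markers in 8 of 9 (median 0.63, camera adjusted p = 0.0344). Immediate early genes were lower in 13 of 16 cases (median -0.16, camera adjusted p = 0.0231). Skeletal muscle genes were higher in 11 of 11 cases (median 3.63, camera adjusted p = 0.00854), in 2 of the 4 libraries: Acta1, skeletal muscle actin, stood at 28.1 CPM in CAL replicate 1 and 74.5 in CAL replicate 2, and at 1.67 or less in CAL replicates 3 and 4 and in the controls. These 4 lists had an adjusted p = 0.690 with an estimated correlation. Macrophage markers were not called (median 0.05, mean -0.03, camera adjusted p = 0.680), with Adgre1 at 477 ± 7.80 and 557 ± 59.4 CPM and Mrc1 at 665 ± 64.1 and 666 ± 28.2. The B cell call ended without control replicate 3 (camera adjusted p = 0.255), without CAL replicate 1 (0.0577) and without the 3 libraries with muscle RNA (0.237), and the muscle call without CAL replicate 2 (0.110). The mast cell call ended without control replicate 2 (0.0913) or 4 (0.0982), CAL replicate 2 (0.113) or 4 (0.191) and the 3 libraries (0.237). The immediate early call ended without control replicate 3 (0.439), CAL replicate 1 (0.0789) or 4 (0.140) and the 3 libraries (0.0666). With the muscle and keratinocyte covariates the B cell, muscle, mast cell and immediate early lists stood at 0.563, 0.683, 0.132 and 0.159, and with the 18S rRNA share the mast cell list at 0.0980.

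**Figure D2:**
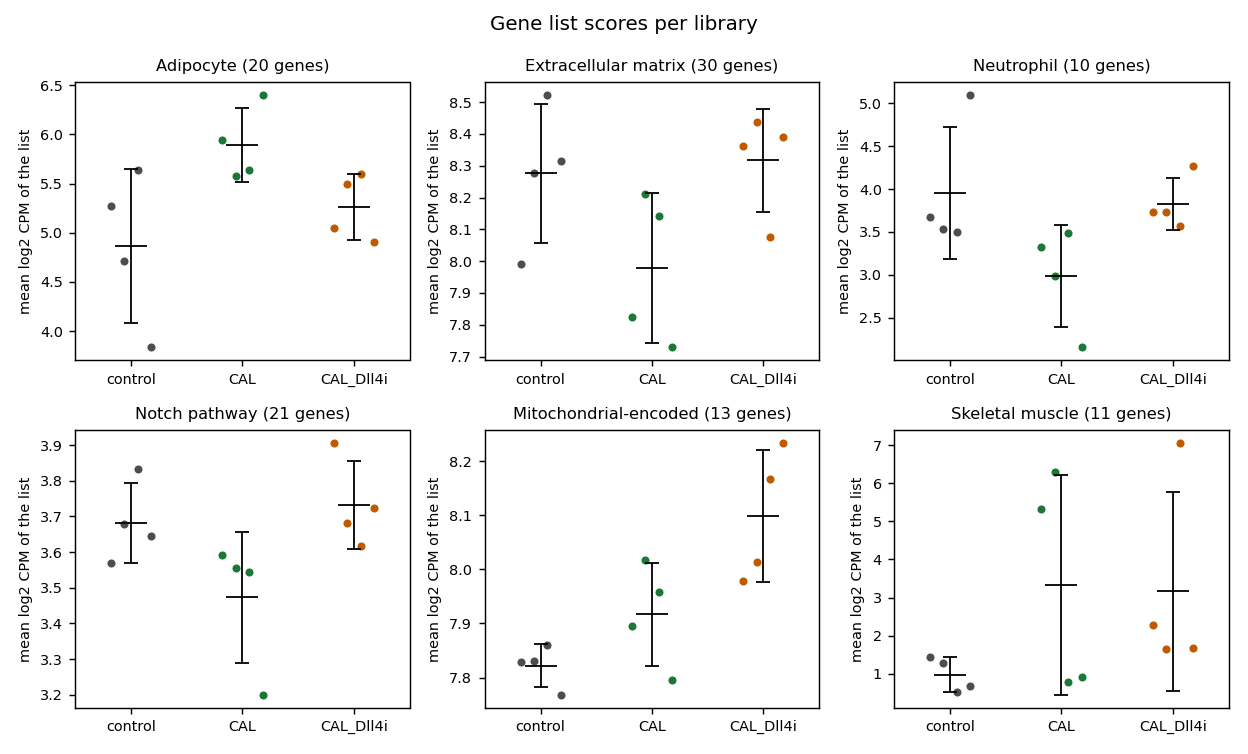
Mean log2 CPM of the genes of 6 lists (vertical axis) in the 4 libraries of each group, with the group mean and SD in black. The adipocyte score is higher in CAL (median log2 fold change 0.95 against control), the matrix and neutrophil scores are lower, and the mitochondrial-encoded score is highest in CAL_Dll4i.

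CAL_Dll4i against CAL asks what Dll4 inhibition adds to grafts with ASC. Adipocyte and lipid synthesis genes had lower estimates with the inhibition, and matrix, Notch and neutrophil genes had higher ones. CAL against control uses the same CAL libraries, so signs opposite to it arise in part without any effect of the inhibition. In simulations of unchanged groups the fold changes of these comparisons correlated at r = -0.504, against -0.561 observed. All 20 adipocyte markers were lower (median -0.67, camera adjusted p = 1.87e-10, adjusted p = 0.442 with an estimated correlation), with Lipe, a lipase gene, at 173 ± 46.3 and 109 ± 19.1 CPM in CAL and CAL_Dll4i and Lep at 19.5 ± 8.27 and 9.43 ± 4.30 (mean ± SD, n = 4 each). All 20 lipogenesis genes were lower (median -0.33, camera adjusted p = 4.68e-11, adjusted p = 0.416 with an estimated correlation), with Acaca at 348 ± 35.4 and 278 ± 33.1 CPM. All 30 matrix genes were higher (median 0.28, camera adjusted p = 1.01e-13, adjusted p = 0.416 with an estimated correlation), with Col1a1 at 1852 ± 316 and 2130 ± 63.3 CPM and Col4a1 at 487 ± 49.4 and 637 ± 90.6. None of these genes passed over all genes or adjusted over the list alone by edgeR, and DESeq2 called none of those named. With the muscle and keratinocyte covariates the adipocyte call ended (camera adjusted p = 0.261).

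No gene was called by edgeR in CAL_Dll4i against CAL, where the smallest adjusted p was 0.659 by its quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 829 genes were higher and 548 lower (7.42%), and the groups did not overlap for 619 genes (3.34%), where chance gives 2.86%. DESeq2 called 1 gene, Vsig8, which was lower (-0.63 ± 0.10, log2 fold change ± SE by edgeR), and voom with sample weights called 0, with 2089 genes at an unadjusted p under 0.05. Vsig8 stood at 27.7 ± 2.32 CPM in CAL and 17.9 ± 1.70 in CAL_Dll4i. The next smallest p-values among lower genes were those of Slc16a10 (-0.31 ± 0.07), Pltp (-0.40 ± 0.09), Ear2 (-0.67 ± 0.15) and Axl (-0.34 ± 0.07). Among higher genes they were those of Phldb2 (0.31 ± 0.07), Mospd4 (1.65 ± 0.37), Lrrc75b (1.15 ± 0.26), Ugt1a2 (0.36 ± 0.08) and Lypd6b (1.36 ± 0.32), and none of these passed by edgeR, DESeq2 or voom with sample weights.

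Notch pathway genes were higher in CAL_Dll4i than in CAL in 17 of 21 cases (median 0.25, camera adjusted p = 0.00019, adjusted p = 0.416 with an estimated correlation). Hes1 stood at 5.22 ± 0.333 and 7.77 ± 1.62 CPM, Nrarp, another Notch target, at 5.68 ± 1.16 and 8.45 ± 2.55, and Efnb2 at 5.34 ± 1.10 and 8.66 ± 1.22. Angiogenic signalling genes were higher in 18 of 26 cases (median 0.05, mean 0.15, camera adjusted p = 0.00893, adjusted p = 0.517 with an estimated correlation), with Vegfa at 18.3 ± 3.60 and 18.9 ± 2.57 CPM, Kdr at 54.3 ± 13.6 and 50.1 ± 2.65 and Angpt2 at 11.4 ± 1.15 and 14.4 ± 2.16. Endothelial markers were higher in 16 of 20 cases (median 0.09, camera adjusted p = 0.0255, adjusted p = 0.685 with an estimated correlation), with Pecam1 at 113 ± 23.5 and 124 ± 13.4 CPM. Lymphatic markers were higher in 7 of 7 cases (median 0.42, camera adjusted p = 0.0016, adjusted p = 0.442 with an estimated correlation). Their mean log2 CPM was -0.08 in CAL replicate 3, 3.09 to 4.03 in the other CAL libraries and 3.07 to 4.27 in CAL_Dll4i. Mural cell markers were higher in 11 of 13 cases (median 0.32, camera adjusted p = 0.0113, adjusted p = 0.517 with an estimated correlation), with the pericyte gene Rgs5 at 21.2 ± 3.41 and 28.3 ± 1.38 CPM. No gene of these 5 lists passed adjusted over its list alone.

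The endothelial call ended without CAL replicate 3 (camera adjusted p = 0.956), CAL replicate 4 (0.136) or CAL_Dll4i replicate 1 (0.406). The lymphatic call ended without CAL replicate 3 (0.577), the mural call without CAL replicate 4 (0.0616) or CAL_Dll4i replicate 1 (0.0535), and the angiogenic call without the 3 libraries with muscle RNA (0.101). With the muscle and keratinocyte covariates the Notch call (0.0512) and the endothelial call (0.133) ended.

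Mitochondrial and immune lists also differed between CAL_Dll4i and CAL. All 13 mitochondrial-encoded genes were higher (median 0.17, camera adjusted p = 8.89e-11, adjusted p = 0.416 with an estimated correlation), 9 of them passed adjusted over the list alone, and COX1 stood at 1164 ± 79.4 and 1354 ± 94.6 CPM. Nuclear genes of oxidative phosphorylation were lower in 18 of 19 cases (median -0.09, camera adjusted p = 1.65e-05, adjusted p = 0.416 with an estimated correlation). Genes of fatty acid oxidation were lower in 17 of 18 (median -0.11, camera adjusted p = 2.5e-05, adjusted p = 0.517 with an estimated correlation). Neutrophil markers were higher in 9 of 10 cases (median 0.74, camera adjusted p = 2.5e-05, adjusted p = 0.416 with an estimated correlation), with S100a8 at 13.3 ± 6.46 and 27.7 ± 4.18 CPM. T and NK cell markers were lower in 19 of 20 (median -0.31, camera adjusted p = 2.91e-05, adjusted p = 0.517 with an estimated correlation), with Gzmb, a cytotoxic protease gene, at 7.91 ± 3.88 and 4.39 ± 1.57 CPM. Interferon response genes were lower in 20 of 20 cases (median -0.41, camera adjusted p = 0.00837) and proliferation genes in 19 of 20 (median -0.10, camera adjusted p = 0.00553), both with an adjusted p = 0.685 with an estimated correlation.

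Of the remaining called lists, immediate early genes were higher in 14 of 16 cases (median 0.12, camera adjusted p = 0.0045) and mast cell markers lower in 8 of 9 (median -0.55, camera adjusted p = 0.00784). Both had an adjusted p = 0.517 with an estimated correlation. The heat shock genes Hspa1a (17.8 ± 8.41 and 36.1 ± 2.89 CPM) and Hspa1b (18.6 ± 8.53 and 37.7 ± 3.65), near-identical copies whose separate counts are uncertain, passed adjusted over the immediate early list alone. Complement and lysosome genes were higher in 18 of 20 cases (median 0.04, camera adjusted p = 0.0119) and red cell genes lower in 7 of 7 (median -0.85, camera adjusted p = 0.00994), and both had an adjusted p = 0.561 with an estimated correlation. Keratinocyte markers were higher in 7 of 8 cases (median 2.27, camera adjusted p = 0.00344, adjusted p = 0.517 with an estimated correlation). Krt14, a basal keratinocyte keratin named after its values were seen, ran from 0.534 to 24.1 CPM in CAL and stood at 167, 61.9, 0.285 and 79.3 CPM in CAL_Dll4i. In control replicates 1 to 4 Krt14 stood at 1.40, 45.1, 6.63 and 78.0 CPM, so it varied widely between libraries of that group too.

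Without CAL replicate 4 the interferon list had a camera adjusted p of 0.389 with the opposite sign, the proliferation list 0.422, the red cell list 0.0614 and the mast cell list 0.0616. Without CAL replicate 2 the red cell list stood at 0.0990 and the mast cell list at 0.0548, and without CAL replicate 1 the complement and lysosome list at 0.289. Without CAL_Dll4i replicate 1 the keratinocyte list stood at 0.0537 and the immediate early list at 0.274. Without CAL_Dll4i replicate 2 the interferon, mast cell and complement lists stood at 0.178, 0.0541 and 0.120. Without CAL_Dll4i replicate 3 the interferon and proliferation lists stood at 0.137 and 0.267, and without CAL_Dll4i replicate 4 the mast cell and complement lists at 0.0832 and 0.108. Without the 3 libraries with muscle RNA the mast cell, red cell and complement lists stood at 0.312, 0.408 and 0.528. With the muscle and keratinocyte covariates the fatty acid oxidation and interferon lists stood at 0.261 each, and the keratinocyte, red cell and immediate early lists at 0.268, 0.883 and 0.121. With the 18S rRNA share the keratinocyte and red cell lists stood at 0.0860 and 0.138.

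**Figure D3:**
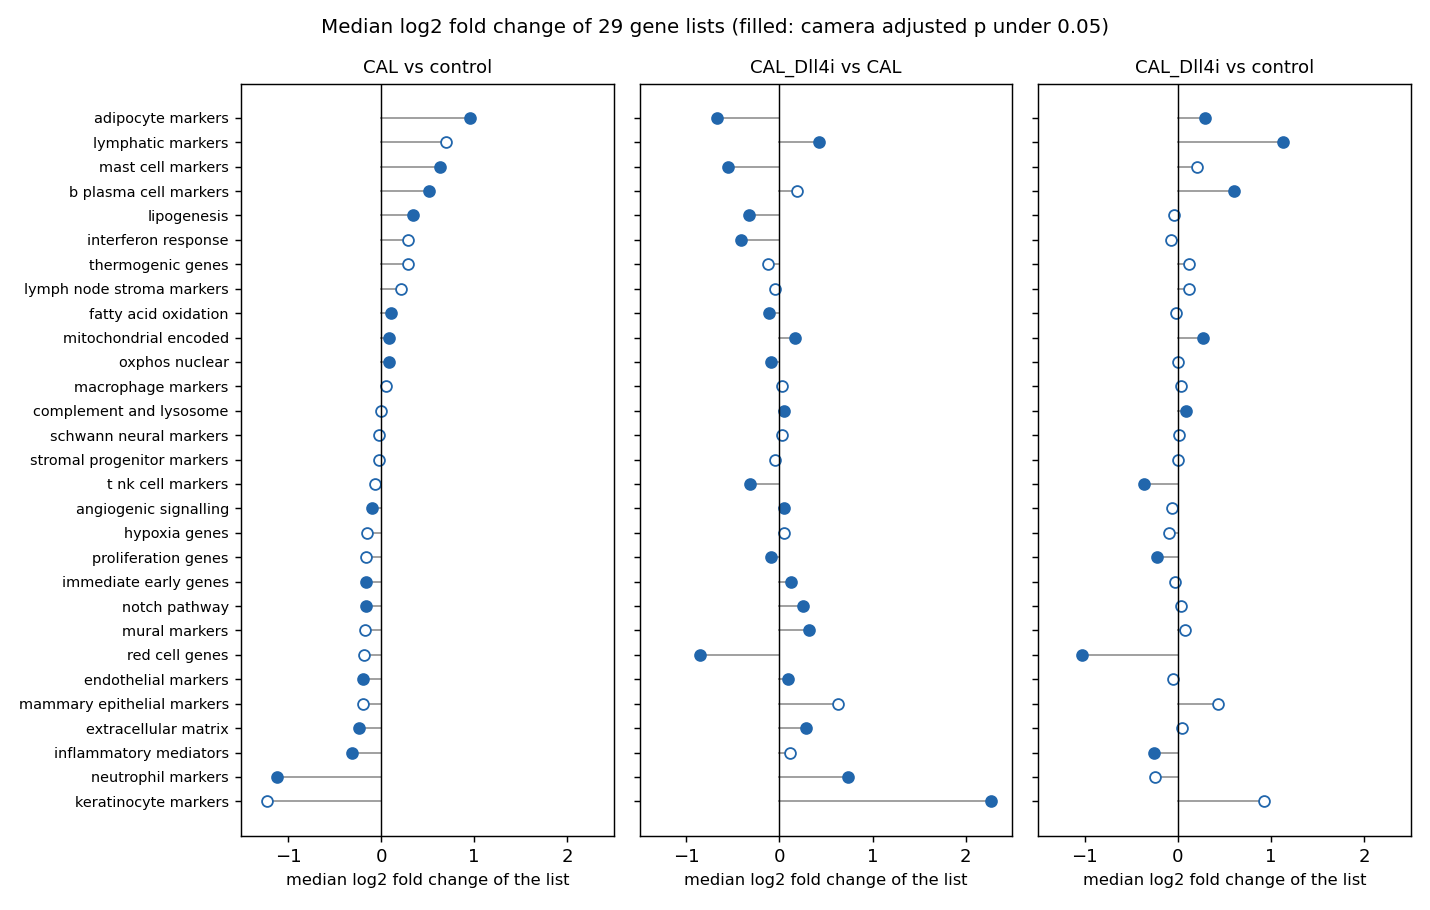
Median log2 fold change (horizontal axis) of the genes of 29 lists in the 3 comparisons, with filled points where the camera adjusted p is under 0.05 at the preset correlation of 0.01 and open points elsewhere. The adipocyte list lies at 0.95, -0.67 and 0.29 and the matrix list at -0.24, 0.28 and 0.05. The same CAL libraries enter CAL against control and CAL_Dll4i against CAL with opposite sign. The muscle list is left out.

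CAL_Dll4i against control asks how grafts with both ASC and Dll4 inhibition differ from control grafts. Mitochondrial-encoded genes were higher in CAL_Dll4i: all 13 had higher estimates (median 0.27) and all 13 passed adjusted over the list alone, against 0 over all genes by edgeR (13 at an unadjusted p under 0.05). DESeq2 called ND1 (adjusted p = 0.00111), COX1 (0.0095), ND4 (0.0115) and ND2 (0.0354). ND1 stood at 475 ± 11.3 CPM in control and 582 ± 32.9 in CAL_Dll4i, and ND4 at 467 ± 11.9 and 576 ± 46.6 (mean ± SD, n = 4 each). The camera adjusted p was 2.41e-19, and the adjusted p = 0.381 with an estimated correlation. All 20 proliferation genes were lower (median -0.22, camera adjusted p = 2.69e-06, adjusted p = 0.788 with an estimated correlation), with Ccnb2, a mitotic cyclin gene, at 12.9 ± 1.73 and 10.2 ± 1.49 CPM. All 20 T and NK cell markers were lower (median -0.36, camera adjusted p = 4.2e-05, adjusted p = 0.788 with an estimated correlation), and Gzma (10.8 ± 3.95 and 4.18 ± 0.215 CPM) was the 1 gene that passed adjusted over that list alone.

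No gene was called by edgeR in CAL_Dll4i against control, where the smallest adjusted p was 0.458 by its quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 716 genes were higher and 568 lower (6.92%), and the groups did not overlap for 884 genes (4.77%), where chance gives 2.86%. DESeq2 called 50 higher and 11 lower, and voom with sample weights called 0, with 2345 genes at an unadjusted p under 0.05. In the simulation of this comparison, with 200 changed genes, DESeq2 made 37 false calls. The smallest p-values among higher genes were those of Hoxb6 (0.91 ± 0.16, log2 fold change ± SE), ND1 (0.29 ± 0.05), Rn7s1 and Rn7s2 (both 1.78 ± 0.31) and Rn7sk (1.22 ± 0.23). Rn7s1 and Rn7s2 are near-identical copies of the signal recognition particle RNA, whose separate counts are uncertain. Among lower genes they were those of Gzma (-1.37 ± 0.25), P2ry12 (-0.53 ± 0.10), Tmem255a (-1.07 ± 0.24), Col8a2 (-1.19 ± 0.27) and Pdk3 (-0.25 ± 0.06), and none of these passed by edgeR. DESeq2 called all 10 (adjusted p = 1.51e-06 for Rn7s1 and Rn7s2 to 0.031 for Tmem255a), and voom with sample weights none.

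Adipocyte markers were higher in CAL_Dll4i than in control in 19 of 20 cases (median 0.29, camera adjusted p = 0.000248, adjusted p = 0.788 with an estimated correlation), with Adipoq at 75.5 ± 34.5 and 94.9 ± 20.8 CPM. The call ended without control replicate 4 (camera adjusted p = 0.498). Lymphatic markers were higher in 6 of 7 cases (median 1.13, camera adjusted p = 0.00847) and B and plasma cell markers in 15 of 16 (median 0.61, camera adjusted p = 0.000376). Complement and lysosome genes were higher in 14 of 20 (median 0.09, camera adjusted p = 0.00357), muscle genes in 11 of 11 (median 3.82, camera adjusted p = 0.00553). Inflammatory mediators were lower in 17 of 20 (median -0.26, camera adjusted p = 0.0229) and red cell genes in 7 of 7 (median -1.03, camera adjusted p = 0.00634). These 6 lists had an adjusted p = 0.788 with an estimated correlation. Prox1, the lymphatic regulator, stood at 1.00 ± 0.354 and 3.46 ± 1.52 CPM, and the inflammatory gene Saa3 at 111 ± 44.4 and 164 ± 20.9. In the muscle list, Acta1 stood at 127 CPM in CAL_Dll4i replicate 3 and at 1.67 to 2.91 in the other 3 libraries of that group. Hba-a1 and Hba-a2 of the red cell list are near-identical copies with uncertain separate counts.

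The muscle call ended without CAL_Dll4i replicate 3 (camera adjusted p = 0.287), the B cell call without control replicate 3 (0.0855), and the red cell call without control replicate 1 (0.0843) or 3 (0.129). The complement call ended without control replicate 1 (0.127) or CAL_Dll4i replicate 2 (0.0509). The inflammatory call ended without control replicate 2 (0.0625), CAL_Dll4i replicate 2 (0.162), 3 (0.251) or 4 (0.0534), and the 3 libraries with muscle RNA (0.153). With the muscle and keratinocyte covariates the lymphatic list stood at 0.150, and the B cell and muscle lists at 0.714 and 0.952 with the opposite sign. With the 18S rRNA share the red cell list stood at 0.267.

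Notch, vascular and matrix lists were not called in CAL_Dll4i against control. The camera adjusted p was 0.914 for Notch genes (median 0.04), 0.337 for angiogenic signalling (-0.06), 0.497 for endothelial markers (-0.05), 0.542 for mural markers (0.07) and 0.0942 for matrix genes (0.05). Matrix genes were higher in 20 of 30 cases, and Col1a1 stood at 1786 ± 158 and 2130 ± 63.3 CPM. That list had camera adjusted p = 0.000236 without control replicate 3, 0.000299 without CAL_Dll4i replicate 3 and 0.000391 without the 3 libraries with muscle RNA. It had 0.0437 with protein-coding genes only. Mural markers had 0.0233 without control replicate 3, and endothelial markers were called lower (0.0136) with the muscle and keratinocyte covariates.

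Fold changes of CAL against control and CAL_Dll4i against control correlated over 18551 genes (Pearson r = 0.621, Spearman rho = 0.555), and 72.2% of genes had the same sign. The comparisons share the control libraries: in 20 simulations with unchanged groups r averaged 0.495 (0.474 to 0.519) and 66.6% of genes had the same sign. Genes were drawn independently there, so the simulated range leaves out variation that genes share. The covariance was 0.0920 against 0.0412 simulated, a difference of 0.0508. With separate control libraries in each comparison r ran from 0.0791 to 0.424 over 6 ways. No gene was called in both comparisons by edgeR, where independent calls give 0. Fold changes of CAL against control and CAL_Dll4i against CAL, which share the CAL libraries, correlated at r = -0.561 (rho -0.544, 29.5% of genes with the same sign) against -0.504 simulated, with a covariance of -0.0786 against -0.0422. With separate CAL libraries that r ran from -0.333 to 0.0120, where CAL replicates 1 and 2 were used in the comparison with control and it lost its negative sign. Genes are not independent replicates, so these values have no p.

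Shares of counts on neighbouring-tissue genes varied between single libraries. Mitochondrial-encoded genes took 0.553 ± 0.0379% of counts in CAL_Dll4i, 0.501 ± 0.0292% in CAL and 0.476 ± 0.00945% in control (mean ± SD, n = 4 each), with all 4 CAL_Dll4i libraries above all 4 controls (two-sided exact permutation p = 0.0286, the smallest possible, and 0.514 adjusted over 21 tests). The other 20 tests, on muscle, keratinocyte, mammary, mesothelial, B cell and red cell genes and on mitochondrial-encoded genes in the remaining comparisons, had an exact permutation p of 0.0571 or more. Muscle genes took 0.277% and 0.454% of counts in CAL replicates 1 and 2, 0.700% in CAL_Dll4i replicate 3 and at most 0.0277% elsewhere. The 3 mesothelial genes took 0.000551% of counts in control, 0.000651% in CAL and 0.000631% in CAL_Dll4i, and the 6 mammary genes 0.00307%, 0.00335% and 0.00389%. 18S rRNA took 4.54 ± 0.792% in control, 5.08 ± 1.10% in CAL and 6.69 ± 1.41% in CAL_Dll4i.

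**Figure D4:**
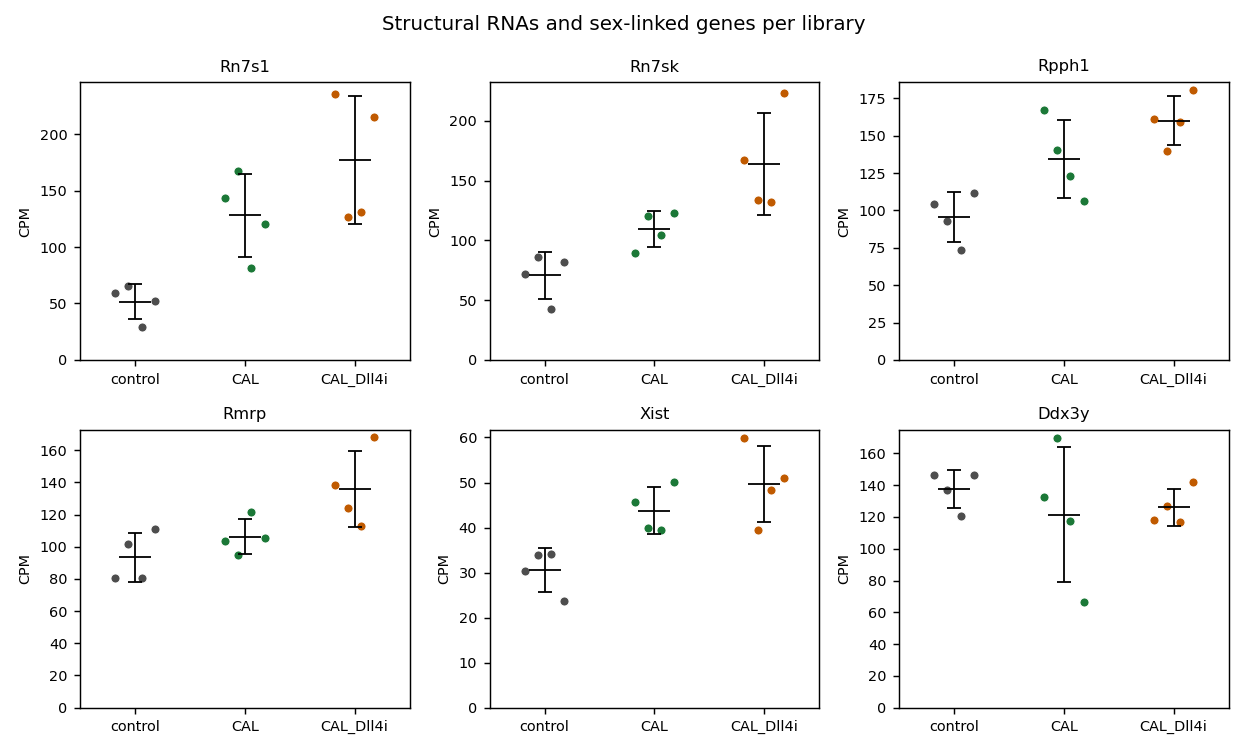
Normalised counts (CPM, vertical axis) of 4 structural RNAs, Xist and Ddx3y in the 4 libraries of each group, with the mean and SD in black. Rn7s1 has its highest value, 236 CPM, in CAL_Dll4i replicate 1, and Ddx3y its lowest, 66.6 CPM, in CAL replicate 4. Rpph1, Rmrp, Xist and Ddx3y were chosen after their values were seen.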

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

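The tests weighed below against muscle RNA, ribosomal RNA and adipocyte share were chosen only after seeing the result. A library was picked out where its gap to the nearest library of its group, over the group's range, was above Dixon's 95% critical value for 4 libraries. This held for 39 of 522 gene and group pairs and 7 of 93 list and group pairs, where chance picks out about 1 in 20 groups. All values are CPM, or mean log2 CPM for a list, with the nearest library of the group in brackets.

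CAL_Dll4i replicate 3 was picked out 12 times, the most of any library. Its muscle genes were the highest of its group: Acta1 127 (2.91), Atp2a1 262 (5.87), Mylpf 91.5 (1.75), Ryr1 102 (5.89), Tnni2 42.6 (1.77), Tnnt3 98.0 (3.95), with the muscle list at 7.06 (2.28) and the thermogenic list at 2.58 (1.94). Its light chain gene Iglc2 was high at 179 (47.6), and Efnb2 at 6.83 (9.13), Fn1 at 1662 (2061) and Pdk3 at 44.0 (47.8) were low.

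CAL replicate 4 was highest of its group for Etfb at 39.0 (34.6), Lep at 31.8 (16.5), Nusap1 at 14.8 (10.1) and the proliferation list at 5.09 (4.81). It was lowest for Phldb2 at 42.2 (48.2) and the Notch list at 3.20 (3.55). CAL replicate 3 was highest for Dsc3 at 1.79 (0.377), Esm1 at 1.43 (0.395) and Ighm at 1304 (430) and lowest for Hba-a2 at 77.7 (220) and the red cell list at 3.32 (5.24). CAL replicate 2 was highest for Ctsk at 277 (220) and lowest for the interferon gene Gbp3 at 47.0 (90.1). CAL replicate 1 was lowest for Atp6v0d2 at 416 (482) and highest for Nrarp at 7.40 (5.35).

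Control replicate 3 was highest of its group for Dusp1 at 77.8 (47.7), Efnb2 at 13.5 (8.32), Il6 at 16.4 (2.03), Ptgs2 at 63.9 (31.4) and the immediate early list at 5.21 (4.64). Control replicate 4 was highest for Ccnb1 at 45.4 and the neutrophil list at 5.10 (3.68) and lowest for Notch4 at 10.5 (12.6) and Sdhc at 54.1 (60.0). Control replicate 1 was lowest for Bgn at 506 (591) and Hdc at 26.3 (52.9) and highest for Notch1 at 143 (126). CAL_Dll4i replicate 1 was highest for the keratinocyte genes Dsc3 at 30.5 (3.67) and Krt79 at 17.96 (3.74) and lowest for ND6 at 54.9 (66.0). Col1a1 was highest in CAL_Dll4i replicate 2 at 2224 (2106) and S100a8 in CAL_Dll4i replicate 4 at 34.0 (26.2).

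Skeletal muscle genes were higher in CAL and CAL_Dll4i than in control. All 10 other muscle list genes had the same 3 highest libraries as Acta1 (CAL replicates 1 and 2 and CAL_Dll4i replicate 3), which is what pieces of skeletal muscle in 3 libraries would give. Only 1 of the 11 genes had all 4 CAL libraries above all 4 controls, which speaks against a change shared by all grafts of the CAL group. CAL_Dll4i was not part of that test. Tnni2, Tnnt3 and Ryr1 had all 4 CAL_Dll4i libraries above all 4 controls, and the other list genes did not. For Tnni2 the lowest CAL_Dll4i value was 1.27 CPM and the highest control value 1.02, so the margin was small.

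Mitochondrial-encoded genes were higher in CAL_Dll4i than in control by camera (adjusted p = 0.381 with an estimated correlation, and 0.0649 by fry), and 5 small structural RNAs, gathered after their values were seen, had higher estimates that did not pass by edgeR (adjusted p = 0.458 to 0.581). With the 18S rRNA share as a covariate the median log2 fold change of the 13 mitochondrial genes was 0.27, the same as without it (camera adjusted p = 6.11e-12 at the preset correlation), which speaks against ribosomal RNA carried into the libraries as its source. Without the 3 libraries with muscle RNA it was 0.26 (camera adjusted p = 4.44e-15), which speaks against muscle tissue. Both results cover the 13 listed genes only. The mitochondrial rRNAs mt-Rnr1 and mt-Rnr2, named after their values were seen, had log2 fold changes of 0.41 and 0.40. With the 18S rRNA share as a covariate these were -0.25 and -0.17. For Rn7s1, Rn7s2, Rn7sk, Rpph1 and Rmrp, the last 2 named after their values were seen, the median was 1.22 before and 0.81 with the covariate, so this test cannot tell. An effect of the treatment on mitochondria could not be separated from other differences between the groups with these data.

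Adipocyte genes were higher and vascular, matrix and neutrophil genes lower in CAL than in control. A larger share of adipocyte RNA alone would leave the ratios between other cell types in place, and the list medians ran from -1.11 (neutrophil) to 0.63 (mast cell). The 5 scores compared were endothelial, neutrophil, B and plasma cell, mast cell and macrophage. Their differences lay further apart than in any other split (sum of squares 1.55, highest other 1.40, exact permutation p = 0.0286, the smallest possible). That met the prediction against adipocyte share as the only source. The test cannot decide this, because its largest difference, neutrophil (-0.96), belongs to the pattern that prompted it. This test was added after the pair of B and plasma cell and endothelial scores, tested first, differed by 0.82 (two-sided exact permutation p = 0.257). Of the 10 pairs, none passed after adjustment (smallest adjusted p = 0.143). Without the 3 libraries with muscle RNA the adipocyte median was 1.06 against 0.95 with them (camera adjusted p = 1.92e-13), which speaks against muscle RNA as the source of the adipocyte values. The lower lists were not part of that test. Without the 3 libraries 8 of the 15 list calls of this comparison were kept, and the angiogenic call ended (camera adjusted p = 0.0643). Better graft survival with ASC may give the same values and was not tested.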

How the results depend on the processing

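The settings with muscle and keratinocyte covariates, without the 3 libraries with muscle RNA (CAL replicates 1 and 2, CAL_Dll4i replicate 3), with the 18S rRNA share and with protein-coding genes only, and the correlation between CAL against control and CAL_Dll4i against CAL, were chosen only after seeing the data. RLE and upper-quartile scaling, no filter, a filter at 1 CPM (15291 genes), summed symbols, neighbouring-tissue genes left out and a fold limit of 1.2 kept the gene counts at 1, 0 and 0. No symbol repeats in the deposited table, so summing symbols changed nothing and tests nothing. Upper-quartile scaling, no filter, DESeq2, voom weights, summed symbols, neighbouring-tissue genes left out and the fold limit were run for gene counts only, not for lists, and each alternative set for a result was run for it. RLE scaling and the filter kept the list counts at 15, 20 and 10. Over all list settings 1385 of 1620 values counted as unchanged, and over named genes 5570 of 5636. A list that changed sign without being called in either setting counted as unchanged. So did 81 sign changes of genes with a main unadjusted p of 0.05 or more. A gene called in neither setting counted as unchanged if it kept its sign, and only Vsig8 was called by edgeR. The high share for genes was therefore largely fixed in advance. With an estimated correlation and by fry, 45 list values each counted as unchanged though every call was lost. These shares do not measure stability. Simulated 1.5-fold changes were recovered in 24.2% to 37.3% of cases by edgeR and 37.3% to 47.8% by DESeq2, which limits what 4 libraries per group show at this depth. False calls numbered 8, 2 and 2 by edgeR and 49, 31 and 37 by DESeq2, so genes called by DESeq2 alone are less certain.

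The CAL against control gene count was 633 by DESeq2, 88 by voom with sample weights, 0 with only the 2 groups and 0 without the 3 libraries with muscle RNA. It was 4 with the covariates (Vsig8, and Fgf10, Smoc1 and Negr1, named after their values were seen) and 0 to 6 with 1 library left out. DESeq2 gave 1 for CAL_Dll4i against CAL and 61 for CAL_Dll4i against control, where leaving out a library gave 0 to 0. List counts ran from 12 to 17, 14 to 20 and 8 to 15 with 1 library left out. They were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry. The estimated correlations of called lists ran from 0.169 (angiogenic, CAL_Dll4i against CAL) to 0.983 (red cell, CAL_Dll4i against control), against the preset 0.01. The adipocyte list had 0.874 in CAL against control. The small camera p-values therefore rest on treating the genes of a list as nearly independent. What set the other differences between settings was not tested.

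With the replicate block the gene counts were 1, 0 and 0 and the list counts 17, 20 and 10, with Vsig8 at adjusted p = 0.0496 in CAL against control. Deviations of log2 CPM from the group mean correlated at -0.385 to 0.144 between libraries with the same number. Of these 12 pairs, 2 lay above 0.1, and 0 libraries correlated best with their own number. The values give no sign of a pairing by number but cannot exclude one.

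Some results turned direction, and the cause was not tested. In CAL the lymphatic list had a mean log2 CPM of -0.08 in replicate 3 and 3.09 to 4.03 in the other libraries. Lymphatic markers in CAL against control had a camera adjusted p of 0.00542 to 0.837 with 1 library left out, turning to higher without CAL replicate 3 and called lower (0.00539) without the 3 libraries with muscle RNA. Interferon genes in CAL_Dll4i against CAL had 1.19e-05 to 0.389, turning without CAL replicate 4. Without the 3 libraries with muscle RNA the muscle list turned in CAL against control (0.883) and in CAL_Dll4i against CAL (6.67e-05), where muscle genes define the libraries left out. In CAL_Dll4i against CAL, thermogenic (0.0241) and mammary (0.0156) genes turned with the covariates. In CAL_Dll4i against control, lipogenesis (1.89e-08), fatty acid oxidation (9.04e-07), oxidative phosphorylation (0.0382), B and plasma cell (0.714), muscle (0.952) and interferon (0.0366) genes did. In CAL against control Atp2a1 had a log2 fold change of -1.24 and Mylpf -0.92 without the 3 libraries, and -0.33 and -0.31 with the covariates. Mylpf had -0.62 in CAL_Dll4i against control with the covariates.

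The correlation of CAL against control with CAL_Dll4i against control was 0.424, 0.364, 0.282, 0.205, 0.0791 and 0.189 with split control libraries and 0.627 at the stricter filter. That of CAL against control with CAL_Dll4i against CAL was 0.0120, -0.225, -0.192, -0.220, -0.256 and -0.333 with split CAL libraries and -0.575 at the stricter filter. Splits halve the shared libraries. Marker shares with an exact p of 0.0286 numbered 0 to 2 with 1 library left out.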

Other observations

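The split tests below had their prediction written before they were run, and the genes named from lists that were not called were chosen only after seeing the result. Of 13 thermogenic genes 8 were higher in CAL than in control, and the list was not called (median 0.29, camera adjusted p = 0.113). Cidea stood at 0.303 ± 0.0442 CPM in control, 0.795 ± 0.209 in CAL and 0.676 ± 0.212 in CAL_Dll4i, Ppargc1a at 2.40 ± 0.643, 6.44 ± 2.26 and 4.29 ± 2.12, and Dio2, a thyroid hormone deiodinase gene, at 15.5 ± 3.78, 9.08 ± 2.07 and 13.7 ± 1.42. All 3 passed adjusted over the list alone in CAL against control, and Cidea also in CAL_Dll4i against control. Among 9 Schwann and neural genes (median -0.02, camera adjusted p = 0.378), 3 passed adjusted over the list alone in CAL against control, among them Ncam1 and Cdh19, with Cdh19 at 3.59 ± 1.69 CPM in control and 1.71 ± 0.190 in CAL. Prlr of the mammary list stood at 4.29 ± 0.543 and 8.91 ± 4.23 CPM, and Gpm6a of the mesothelial list at 2.22 ± 0.523 and 3.94 ± 1.52, and each passed adjusted over its list alone. None of these genes passed over all genes by edgeR.

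Stromal progenitor markers were not called in any comparison (median -0.02, -0.05 and 0.01, camera adjusted p = 0.898, 0.728 and 0.914), with Pdgfra at 213, 210 and 245 CPM in control, CAL and CAL_Dll4i. Macrophage markers had a camera adjusted p of 0.350 in CAL_Dll4i against CAL (median 0.02) and 0.142 against control (0.04). Lymph node stroma genes had 0.811, 0.884 and 0.579 (median 0.21, -0.05 and 0.12), and hypoxia genes 0.0607, 0.448 and 0.142 (-0.15, 0.05 and -0.09). Mammary genes had 0.655, 0.919 and 0.497 (-0.20, 0.63 and 0.43), thermogenic genes 0.728 and 0.0942 in the comparisons with CAL_Dll4i (-0.12 and 0.12), and Schwann genes 0.668 and 0.514 there (0.02 and 0.02).

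In CAL against control, lists that were not called were lymphatic (median 0.70, camera adjusted p = 0.811), mural (-0.17, 0.219), T and NK cell (-0.07, 0.898), keratinocyte (-1.23, 0.340), red cell (-0.18, 0.811), proliferation (-0.16, 0.111), interferon (0.29, 0.184) and complement and lysosome genes (0.00, 0.680). In CAL_Dll4i against CAL they were inflammatory (0.11, 0.168), B and plasma cell (0.19, 0.728) and muscle genes (0.17, 0.728). In CAL_Dll4i against control they were lipogenesis (-0.04, 0.964), fatty acid oxidation (-0.02, 0.964), oxidative phosphorylation (0.00, 0.964), neutrophil (-0.24, 0.579), mast cell (0.21, 0.964), keratinocyte (0.93, 0.0942), immediate early (-0.03, 0.926) and interferon genes (-0.07, 0.514). The 3 mesothelial genes were too few to test (median 0.82, -0.35 and 0.47).

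Several of these lists were called under an alternative, given here as camera adjusted p. In CAL against control, interferon genes were called higher with the replicate block (0.0282), without control replicate 2 (0.0130), CAL replicate 2 (0.00272), CAL replicate 3 (0.0482) or the 3 libraries with muscle RNA (0.000625), and with the muscle and keratinocyte covariates (0.00227). Proliferation genes were called lower with the block (0.0375), without control replicate 3 (0.000883) or CAL replicate 4 (0.00177) and with the 18S rRNA share (0.00914). T and NK cell markers were called lower without control replicate 3 (0.00436), hypoxia genes without control replicate 1 (0.0297) or CAL replicate 3 (0.000605), and mural markers without control replicate 1 (0.0127) or the 3 libraries (0.0193). Red cell genes were called lower with the covariates (0.0448), and thermogenic genes higher with only the 2 groups (0.04999).

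In CAL_Dll4i against CAL, inflammatory mediators were called higher without CAL replicate 3 (0.00812) or CAL_Dll4i replicate 2 (0.0397) or 3 (0.0485), B and plasma cell markers without CAL_Dll4i replicate 2 (0.0144), hypoxia genes without CAL replicate 3 (0.00262) and stromal markers with the covariates (0.0423). Muscle genes were called lower without CAL_Dll4i replicate 3 (0.0153).

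In CAL_Dll4i against control, keratinocyte markers were called higher without control replicate 2 (0.0405) or 4 (0.0189), CAL_Dll4i replicate 3 (5.85e-05) or the 3 libraries (0.000504). Macrophage markers were called higher without control replicate 3 (0.0233) or CAL_Dll4i replicate 1 (0.0330), with the covariates (0.0180) and with the 18S rRNA share (0.0289). Thermogenic genes were called higher without control replicate 3 (0.0333) or CAL_Dll4i replicate 4 (0.0496) and with the covariates (0.000610). Mammary genes were called higher without CAL_Dll4i replicate 3 (0.0373) or the 3 libraries (0.0206), and stromal (0.0469) and immediate early genes (0.0380) without control replicate 3. Interferon genes were called lower without control replicate 3 (0.0419) or CAL_Dll4i replicate 4 (0.0431) and with the 18S rRNA share (0.00179), and hypoxia genes without control replicate 1 (0.0481) or CAL_Dll4i replicate 4 (0.0431). Lipogenesis genes were called lower without control replicate 4 (0.0189) and neutrophil markers with the covariates (0.00129).

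In lists that were not called, median, mean and test differed in sign in 12 cases. In CAL against control the lymphatic list had median 0.70 and mean 0.71 with a test towards lower, the macrophage list median 0.05 and mean -0.03, and the mammary list median -0.20 and mean 0.01, both with a test towards higher. In CAL_Dll4i against CAL, thermogenic (median -0.12, mean 0.01) and muscle genes (median 0.17, mean 0.22) had a test towards lower, and stromal (-0.05, 0.01) and lymph node genes (-0.05, 0.04) towards higher. In CAL_Dll4i against control, lipogenesis (-0.04, 0.07), fatty acid oxidation (-0.02, 0.01) and Schwann genes (0.02, -0.05) had a test towards lower, and stromal (0.01, -0.01) and immediate early genes (-0.03, 0.02) towards higher.

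Xist, expressed from the inactive X chromosome of female cells, ran from 23.7 to 59.8 CPM over all 12 libraries, and the Y chromosome gene Ddx3y from 66.6 to 170, so each library held RNA of both kinds. Both were named after their values were seen. Xist stood at 30.5 ± 4.84 CPM in control, 43.8 ± 5.15 in CAL and 49.7 ± 8.39 in CAL_Dll4i. Rn7s1 stood at 51.6 ± 15.7, 128 ± 36.5 and 177 ± 56.5 CPM, Rn7sk at 70.7 ± 19.5, 109 ± 15.3 and 164 ± 42.6, and Lars2, also named after its values were seen, at 1489 ± 297, 1738 ± 303 and 2283 ± 651.

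The 8 libraries of each comparison can be split 4 against 4 in 35 ways, of which the real groups are 1. Each number of splits given below counts those with as many or more and includes the real groups themselves. In CAL against control, 3 splits gave as many called genes as the real groups (1, highest other 6), 2 as many genes at an unadjusted p under 0.05 (2705, highest other 2825) and 12 as many lists (15, highest other 19), so chance is not excluded. With 0 called genes in both comparisons with CAL_Dll4i, all 35 splits give as many by construction (0, highest other 0), which tests nothing. In CAL_Dll4i against CAL, 5 splits gave as many at an unadjusted p under 0.05 (1377, highest other 2666) and 2 as many lists (20, highest other 23). In CAL_Dll4i against control the numbers were 7 (1284, highest other 2961) and 26 (10, highest other 19). By DESeq2, only the real groups reached 633 called genes in CAL against control (1 split of 35, highest other 492). This was the 1 count of 10 that met the prediction against chance. It is the lowest share that 35 splits can give and was not adjusted over the 10 counts, so chance is not excluded. At an unadjusted p under 0.05 DESeq2 gave 2927 genes with the real groups and 3099 with control replicate 1 put with CAL replicates 1, 2 and 4, so chance is not excluded for that count. The split with 6 genes put control replicate 3 with CAL replicates 1, 2 and 4, and that with 2825 put control replicate 1 with them. The split with 2666 put CAL_Dll4i replicate 3 with CAL replicates 1, 2 and 4, and that with 2961 put control replicates 1 and 4 with CAL_Dll4i replicates 1 and 3. Splits that call more than the real groups point to a structure of the samples, and what sets it was not tested. The first principal component held 25.8% of variance and the second 17.3%. On the first, CAL replicates 1, 2 and 4 and CAL_Dll4i replicate 3 scored -43.2, -25.7, -31.6 and -44.7. CAL replicate 3 scored 7.44 there, and all libraries of both kinds other than those named lay between -3.89 (control replicate 1) and 33.9 (control replicate 3).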
